A study of Homo sapiens with 4 samples.

How the data were processed

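Single-cell RNA sequencing was made from bronchoalveolar lavage cells of healthy volunteers, in 4 libraries of 1 group with the 10x Chromium 3' v2 chemistry, per the labels. Per the labels' protocols, airspaces were washed with saline, and the fluid was kept on ice, filtered and spun, with red cells lysed where needed. The deposited matrices hold raw UMI counts per gene and cell barcode for 33694 genes, made by the authors with Cell Ranger 3.1.0 on GRCh38, per the submitters' processing notes. They are the matrices of barcodes that Cell Ranger called as cells, and the smallest barcode held 500 UMIs. The annotation release and sequencing depth in reads are not given in the sources used here. Gene positions come from GENCODE release 29, matched by gene identifier, which may differ from the release the authors used. The barcode and gene name files carry no measurement. All libraries were checked against each other: the chi-square per degree of freedom between count profiles of 2 libraries lay between 97.6 and 222, and 1.23 to 2.13% of barcode sequences of the smaller library recurred in the other, so no file was a copy of another.

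Library totals ranged from 47054609 to 66879421 UMIs. Barcodes with at least 500 UMIs, at least 200 genes and under 15% of UMIs from mitochondrially encoded genes were kept. Of 47317 barcodes, 1048 had too few genes, and 2873 of the rest had too high a mitochondrial share. Some of these 2873 were also among the doublets described next. Doublets were scored per library with Scrublet, as in scanpy, at an expected rate of 0.08. Its automatic threshold called 10, 0, 2169 and 2794 barcodes in the 4 libraries, which is no stable rate, so the top 8% of scores per library were left out instead, 3699 barcodes in all; this was decided after the data were seen, and the automatic threshold was run as an alternative. Kept cells numbered 11594, 11422, 8011 and 8702, of which 7875, 9334, 6867 and 7650 were macrophage-like. Median depths of macrophage-like cells were 6336, 3702, 7069 and 6247 UMIs, and of other cells 911, 700, 929 and 1020 UMIs.

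Counts were scaled to 10000 per cell and log-transformed after adding 1. Chemokine and chemokine receptor genes, mitochondrially encoded, ribosomal protein, immunoglobulin, T cell receptor and sex-linked marker genes were left out of the clustering. The 2000 most variable genes were scaled within each library, and 30 principal components with 15 neighbours were clustered by the Leiden method at a resolution of 1. Clusters were named from 17 marker lists of 125 genes. The marker lists, the gene lists and the comparisons with their tests and thresholds were chosen before the data were examined. The doublet limit, the rule that turns markers into names, the tests of handling, doublets, free RNA and barcodes almost free of mitochondrial transcripts, the randomly drawn classes, and the swapped-class tests of the 3 macrophage comparisons were set or revised after the data were seen. A list was considered when the mean share of cells with a UMI of its genes reached 0.55 of the best list's. The highest mean log2 ratio to the mean of all clusters (20 CPM added to both sides) gave the name. At least 3 markers of that list had to be detected. Shallow clusters without a marker among their leading genes, cycling mixtures and clusters almost free of mitochondrial transcripts stayed unnamed. All names are likenesses to marker lists.

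Each macrophage-like cell was thinned once, with a fixed seed, to 2000 UMIs; 1964 of 31726 were shallower and left out of the classes. MIP-1-high cells had at least 3 UMIs of CCL3, CCL4 and their near-identical copies after thinning. The class is a range of a count and not a cell type, and 239 of its 1188 cells had exactly 3 UMIs. Near-identical copies share reads that a unique alignment discards, so MIP-1 counts are lower limits, and values for CCL3 and CCL4 singly depend on how reads were assigned among the copies. Interferon-high and metallothionein-high cells lay above the 90th percentile of their library in UMIs of the respective list, which was 5.8 to 11 UMIs for the interferon list and 3 to 7 for metallothioneins.

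Full counts were summed per library and class and fitted with edgeR 4.0.16, with genes kept by filterByExpr, TMM scaling, library as block and the two-sided quasi-likelihood F test. The genes that define a class were taken out of its counts before fitting. The Benjamini-Hochberg threshold was 0.05 over all genes tested, and each list's calls are also given with the adjustment over the list alone. The SE of a log2 fold change was taken as its size divided by the root of the F statistic. It rests on a spread that edgeR moderates over genes, fully in the MIP-1-high fit (infinite prior degrees of freedom) and with 36.3 and 25.9 prior against 3 residual degrees of freedom in the interferon-high and metallothionein-high fits, so it can be smaller than the SE between libraries. Ranges over libraries are of log2 CPM differences with 2 counts added. CPM means are over libraries. For chemokine genes, each population with at least 20 cells in at least 3 libraries was compared with macrophages in 1 fit. Programme lists, 27 lists with 443 genes of which 3 are not in the files, were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Lists share genes with each other, and macrophages express several genes of the neutrophil and T cell marker lists. Genes named in the text were fixed by rule: the 15 largest increases and 10 largest decreases (8 and 5 in the interferon-high and metallothionein-high comparisons) among genes past the threshold, at 10 CPM or more in either class on average and with 1 direction in all libraries, up to 4 members per list with the smallest p, and for chemokines CCL3, CCL4, CCR1 and the 3 largest increases per population. The rule left out genes without a symbol, genes with germline presence or copy number variation, and sex-linked genes. FOS, JUN, ISG15, IFI6 and IFIT1 are named outside it, as single genes of their lists.

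For the clusters, the macrophage cluster with the highest MIP-1 CPM in the other 3 libraries was chosen for each library in turn, and its share of MIP-1-high cells was compared with its share of macrophages by an exact sign-flip test. Intervals are exact binomial (Clopper-Pearson) at 95%, and like limits from a count of 0, taken as 3 counts, they cover counting error only.

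The fit was tested on simulated counts with the depth of each comparison, its common spread given to every gene, and 200 genes changed. Differences between genes in their spread between libraries were not simulated, so the false calls below do not cover them. For MIP-1-high cells 80.0% of genes raised by 1 log2 unit, 75.0% of genes lowered by 1, 100.0% of genes raised by 2 and 77.6% of genes lowered by 2 were recovered, with 5 unchanged genes among 169 calls. For interferon-high cells the shares were 92.0, 71.4, 100.0 and 87.5%, with 9 unchanged genes among 182 calls. For metallothionein-high cells they were 89.8, 68.8, 100.0 and 95.6%, with 6 among 176.

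Alternatives, chosen before the data were examined except where stated, were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, no block, mitochondrial limits of 10 and 25%, doublets kept, at least 1000 UMIs, Leiden resolutions of 0.5 and 2, chemokine genes kept in the clustering, MIP-1-high from 1 or 10 UMIs or above the 90th percentile, thinning to 1000 UMIs or none, other macrophages of the same depth or without MIP-1 UMIs, a fit within clusters, and each replicate left out. A fit with limma voom and robust moderation of the spread was added after the data were seen. The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3. Gene-level results of single germline-variable genes and of sex-linked genes are not given, and some genes that the rule names are not reported here.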

Results

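Bronchoalveolar lavage washes out the cells that line the airspaces, most of them alveolar macrophages, with lymphocytes, dendritic cells and shed epithelium beside them. MIP-1 is a pair of chemokines, CCL3 and CCL4, that attract leukocytes through receptors such as CCR1. The series title asks about a macrophage subtype that expresses MIP-1, and the labels hold 1 group, so cell classes were compared within each of the 4 libraries from healthy volunteers, called replicates 1 to 4. The labels do not state that the libraries came from separate persons, so p-values speak for these libraries only. The spread they rest on was pooled over genes of similar abundance, in part or fully, and was often smaller than a gene's own spread between libraries.

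The deposited count matrices held 13992, 13244, 9302 and 10779 barcodes in replicates 1 to 4, with 65867212, 47054609, 61911749 and 66879421 UMIs. After filtering, 39729 of 47317 barcodes remained and fell into 22 clusters. Macrophage-like cells, named from MARCO, FABP4, the C1Q genes and other markers, made up 80.8% ± 8.97 (SD, n = 4) of kept cells, from 67.9 to 87.9%. T cell-like cells made up 11.02% ± 6.08, from 5.61 to 19.7%. NK cell-like cells held 2.34% ± 0.675, dendritic-like cells 1.23% ± 0.236, secretory epithelium-like cells 1.02% ± 0.522, B cell-like cells 0.836% ± 1.36 and ciliated epithelium-like cells 0.774% ± 0.404, all as SD over n = 4 libraries. Unnamed clusters held 1.96% ± 3.02. No cluster took the NK cell-like name when cells under 1000 UMIs were left out or at a Leiden resolution of 0.5. The NK cell-like cluster was led by GNLY, NKG7, KLRC1 and KLRD1, but also by CD8B, ZNF683 and the T cell marker CD8A. NK cell-like cells may thus include T cells, here and in all comparisons below.

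NK cells and T cells are known sources of CCL3 and CCL4 besides macrophages. In these lavages NK cell-like cells carried the highest MIP-1 level per UMI, yet macrophages, being deeper and far more numerous, held most of the MIP-1 transcripts. CCL3 (ENSG00000277632, chromosome 17, 36088256 to 36090169, minus strand, GRCh38) and CCL4 (ENSG00000275302, chromosome 17, 36103590 to 36105621, plus strand) are neighbouring protein-coding genes, and both have near-identical copies that were summed with them as MIP-1. Summed MIP-1 reached 1464 ± 1312 counts-per-million (CPM; SD, n = 4) in NK cell-like cells, from 521 CPM to 3391 CPM in replicate 4. It was 222 ± 65.8 CPM in T cell-like cells and 205 ± 124 CPM in macrophages, where it ranged from 59.8 to 339.5 CPM. Secretory epithelium held 117 ± 112 CPM, dendritic-like cells 75.4 ± 72.8 CPM and ciliated epithelium 66.8 ± 58.3 CPM. Macrophages held 93.1% ± 2.14 of all MIP-1 UMIs, NK cell-like cells 3.23% and T cell-like cells 2.60%. After each cell was thinned to 500 UMIs, 30.3% ± 10.4 of NK cell-like cells, 7.68% of T cell-like cells and 5.24% ± 3.05 of macrophages had a MIP-1 UMI, against 1.92% of secretory and 1.32% of ciliated cells, which should lack the genes. Median depths before thinning were 783, 867, 6291, 2196 and 3459 UMIs in that order. FTL, an iron store transcript abundant in macrophages, stood at 64.9% of its macrophage level in secretory cells, at 34.1% in ciliated cells and at 17.7% in T cell-like cells. The lipid gene APOC1 stood at 61.5%, 31.5% and 15.8%, and CCL3 at 57.3%, 40.5% and 65.5%. Secretory cells thus held more of these 2 macrophage transcripts than ciliated cells.

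**Figure D1:**
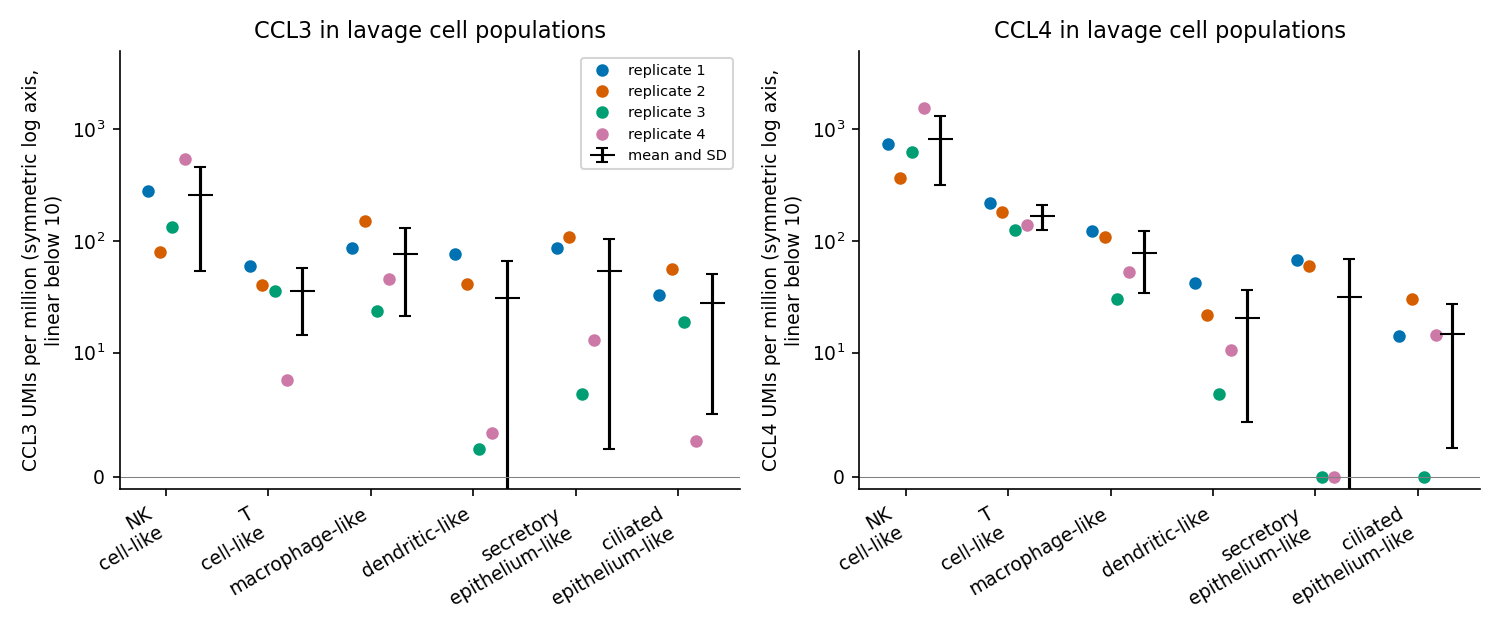
CCL3 and CCL4 in CPM (symmetric log axis, linear below 10) in each population, with a point per replicate and bars for the mean and SD of the 4 libraries. CCL4 averaged 814 CPM in NK cell-like cells and 78.5 in macrophages, and CCL3 256 and 76.2.

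Chemokine genes of each population differed from those of macrophages, and several were shared between populations; the populations were not tested against each other. NK cell-like cells were higher than macrophages in XCL1 and XCL2, which attract cross-presenting dendritic cells, and in CCL5, a chemokine of cytotoxic lymphocytes. T cell-like cells were higher in XCL1, in CXCR3, the receptor for interferon-induced chemokines, and in the lymph node homing receptor CCR7. Dendritic-like cells were higher in CCR7 and in the CCR4 ligands CCL17 and CCL22. Secretory cells were higher in CXCL17, CXCL6 and CXCL1, and ciliated cells in CXCL17, CXCL6 and the scavenging receptor ACKR4. Of 29 chemokine genes tested among 6345 genes (edgeR quasi-likelihood test, library as block, Benjamini-Hochberg), 12 were higher and 11 lower in T cell-like cells than in macrophages, also 12 and 11 adjusted over the list alone. In NK cell-like cells 12 were higher and 8 lower (13 and 9 adjusted over the list alone), in dendritic-like cells 10 and 9 (11 and 9), in secretory cells 3 and 9 (3 and 9), and in ciliated cells 5 and 13 (5 and 13). The counts of epithelial cells depended on single libraries: higher in ciliated cells were 2 without replicate 4, and in secretory cells 5 without replicate 2 and 2 without replicate 4. Lower in secretory cells were 5 without replicate 3, 4 without replicate 4 and 2 with the DESeq2 test. XCL2 was higher in NK cell-like cells by 9.69 ± 0.44 log2 units (SE, n = 4; adjusted p = 2.7e-14), CCL17 in dendritic-like cells by 9.50 ± 0.40, CXCR3 in T cell-like cells by 7.77 ± 0.34, CXCL17 in secretory cells by 9.45 ± 0.37 and ACKR4 in ciliated cells by 8.70 ± 0.61. Macrophage levels of these genes were very low, at 0.22, 0.73, 0.44, 0.50 and 0.06 CPM in that order, so the sizes are uncertain. CXCL6 in ciliated cells rested on 13 UMIs (4.64 CPM, SD 5.36).

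The MIP-1 receptor CCR1 (ENSG00000163823, chromosome 3, 46201709 to 46208396, minus strand) was higher in macrophages than in lymphocytes and epithelium, while CCL4 was higher in NK cell-like cells. CCL4 was higher in NK cell-like cells than in macrophages by 3.11 ± 0.37 log2 units (SE, n = 4; edgeR adjusted p = 3.4e-08), and CCL3 by 1.55 ± 0.44 (adjusted p = 0.00453), which fell to 0.73 and was no longer past the threshold without replicate 4. In T cell-like cells CCL4 was higher by 0.86 ± 0.35 (adjusted p = 0.0348), not past without replicate 3 (0.59), and CCL3 lower, at -1.27 ± 0.45 (adjusted p = 0.0151), not past without replicate 2 (-0.84). CCL3 in T cell-like cells turned to 0.40 with cells of at least 1000 UMIs only and to 0.03 at a Leiden resolution of 0.5. CCL3 was lower in dendritic-like cells (-1.52 ± 0.54, adjusted p = 0.0321), not past without replicate 2 (-1.14) or replicate 3 (-1.49). CCL4 was lower in dendritic-like (-2.16), secretory (-1.83) and ciliated cells (-3.23), and CCL3 in ciliated cells (-2.51), while CCL3 in secretory cells was not past the threshold (adjusted p = 0.297). CCL4 in secretory cells was not past without replicate 3 (-1.72) or replicate 4 (-1.19). With the DESeq2 test the calls of CCL3 and CCL4 in T cell-like cells (-1.13 and 1.12), CCL3 in dendritic-like cells (-1.91) and CCL4 in secretory cells (-1.69) kept their direction and were not past the threshold. CCR1 was lower in T cell-like (-2.90), ciliated (-2.64), NK cell-like (-1.27) and secretory cells (-1.12), the last not past without replicate 3 (-0.97), without replicate 4 (-0.87) or with the DESeq2 test (-0.85), and not past in dendritic-like cells (adjusted p = 0.347).

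A minority of alveolar macrophages showed several MIP-1 UMIs at equal depth, while most showed 0, which at this depth does not mean that the cell lacked the transcript. Without thinning, 9.55 to 27.97% of macrophages per library showed at least 1 MIP-1 UMI. With each macrophage thinned to 2000 UMIs, cells with at least 3 MIP-1 UMIs, called MIP-1-high, made up 4.57% of macrophages in replicate 1 (exact binomial 95% interval 4.10 to 5.08), 6.61% in replicate 2 (6.08 to 7.16), 1.23% in replicate 3 (0.980 to 1.53) and 2.99% in replicate 4 (2.61 to 3.40). The mean was 3.85% ± 2.29 (SD, n = 4), from 334, 548, 82 and 224 cells of 29762. The intervals of the 4 libraries did not overlap, so the libraries differed by more than counting error. MIP-1-high cells held 75.0% ± 8.31 of the thinned MIP-1 UMIs, 88.4% ± 6.25 of macrophages showed 0, and 7.71% ± 4.11 had 1 or 2. The same count was reached by 1 of 207 ciliated cells (0.483%, interval 0.0122 to 2.66), 4 of 333 dendritic-like cells (1.20%, 0.328 to 3.05), 4 of 197 secretory cells (2.03%, 0.556 to 5.12) and 1 of 38 B cell-like cells (2.63%, 0.0666 to 13.8). It was also reached by 7 of 110 T cell-like cells (6.36%, 2.60 to 12.7) and 3 of 15 NK cell-like cells (interval 4.33 to 48.1%), so it is not special to macrophages. These intervals pool all libraries. The pooled ciliated interval lay below the macrophage shares of replicates 1, 2 and 4, and the pooled dendritic-like interval below those of replicates 1 and 2. By library, however, ciliated intervals reached up to 12.3, 11.1, 9.25 and 3.89% in replicates 1 to 4, and each held that library's macrophage share. Dendritic-like intervals reached 7.13% in replicate 1 and 8.16% in replicate 2, and also held the macrophage shares there. The secretory interval held the macrophage shares of replicates 1, 3 and 4, and in replicate 2, where 3 of 52 secretory cells reached the count (5.77%, 1.21 to 15.9), that library's own interval held its share. Within single libraries the macrophage share was thus not told apart from the ciliated, dendritic-like or secretory share in these counts. The spread of MIP-1-high cells over macrophage clusters, by contrast, was uneven in each library. In replicate 3 the cluster with the most MIP-1 transcripts held 65.9% of MIP-1-high cells and 5.91% of macrophages, and 13.7% of its cells were MIP-1-high against 0.447% in other clusters. MIP-1-high and other macrophages had median depths of 5774 ± 1245 and 5978 ± 1429 UMIs.

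The macrophage cluster with the most MIP-1 transcripts was set apart by the manganese superoxide dismutase gene SOD2 and by TNFAIP6, TNIP3, S100A8, IL1B and ICAM1, most of them NF-kB targets; chemokine genes had no part in the clustering. A small cluster marked by APOC2 and SLC1A3, with SOD2 among its leading genes, came second on average. It had the highest median doublet score of all clusters (0.213). A cluster marked by SPP1, RNASE1 and LGMN carried more than most others, and a cluster marked by MCEMP1, RETN, INHBA and FBP1 carried little. The SOD2 cluster of 3270 cells held 1097 ± 410 CPM of MIP-1 (SD, n = 4), from 537 to 1438 CPM, against 428 ± 400 CPM in the APOC2 cluster of 244 cells, from 46.0 to 985 CPM, 219.7 ± 134 CPM in the SPP1 cluster and 58.6 CPM in the MCEMP1 cluster. The APOC2 cluster stood above the SPP1 cluster in replicates 1, where it held 20 cells, and 4. It did not in replicates 2 (403.2 against 404.0 CPM) and 3 (46.0 against 91.2 CPM). Chosen for each library from the other 3, the cluster with the most MIP-1 transcripts was the SOD2 cluster 4 times of 4. The SOD2 cluster held 66.1% ± 10.5 of MIP-1-high cells and 10.3% ± 4.24 of macrophages, a difference of 55.8 ± 9.79 percentage points, from 41.5 to 63.5 and positive in 4 of 4 libraries. The exact sign-flip permutation test, two-sided, gave p = 0.12, the smallest that 4 libraries allow, so it could not pass the threshold. Of the cells in this cluster 22.9% ± 6.75 were MIP-1-high, against 1.55% ± 1.34 in the other clusters, so most of its cells were not.

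**Figure D2:**
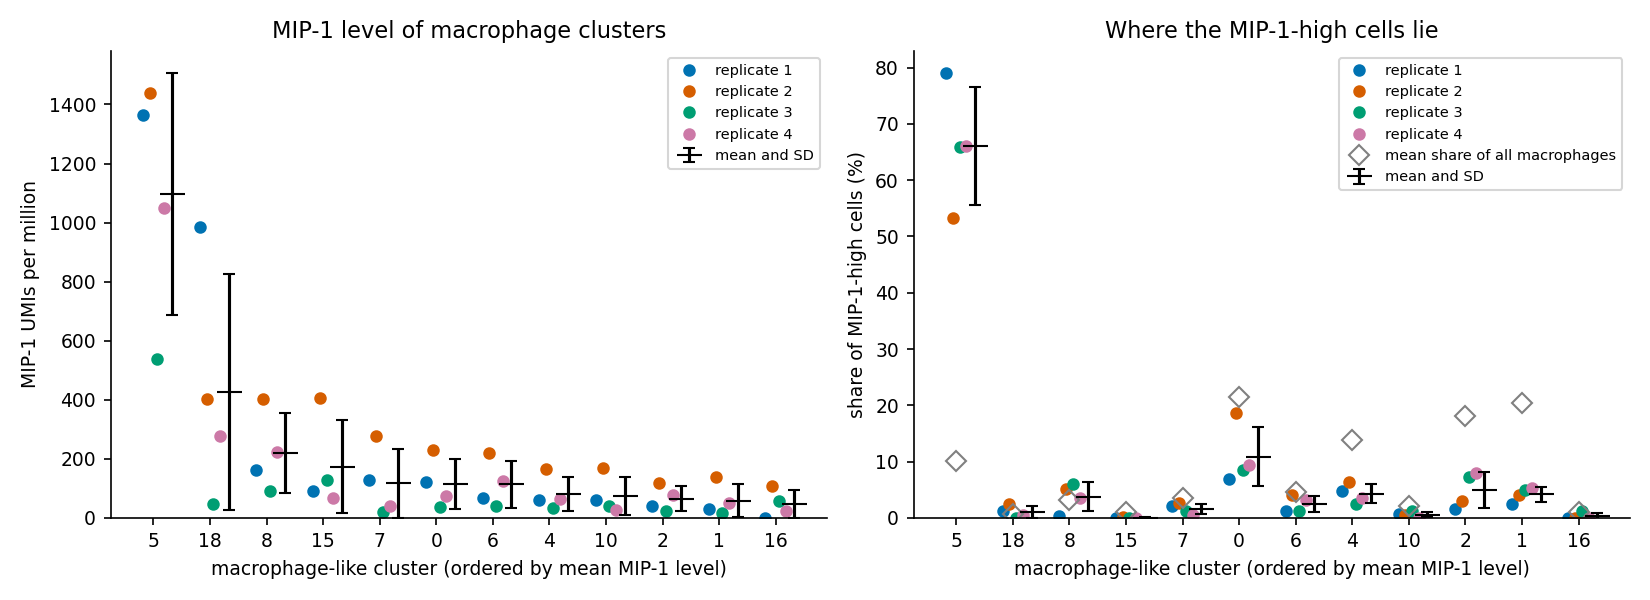
MIP-1 CPM in each macrophage cluster (left) and the share of MIP-1-high cells, in percent, that each cluster held (right), with a point per replicate; open diamonds give each cluster's mean share of all macrophages. The SOD2 cluster, shown as cluster 5, stands highest in both panels, at 1097 CPM and 66.1% of MIP-1-high cells.

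MIP-1-high macrophages carried a broad inflammatory set. They were higher in CCL20, which attracts CCR6-bearing lymphocytes and dendritic cells, in the neutrophil chemokines CXCL8 and CXCL1, in the cytokines IL1B and TNF and in CXCL10, and in the NF-kB genes TNIP3, NFKB2, ICAM1, G0S2, PTX3 and TNFAIP6. MIR3142HG, the host transcript of the microRNA miR-146a, DUSP2 and SHROOM3 completed the 15 largest increases. They were lower in the proliferation factor MYB, in ID3 and ECSCR, in the insulin and growth factor genes IGF1 and IRS2, in the fuel switch kinase PDK4, and in PDGFD, MAST4, CACNB3 and AQP3. Of 12204 genes tested (edgeR quasi-likelihood test, library as block, Benjamini-Hochberg; MIP-1 genes taken out), 762 were higher and 583 lower. CCL20 (ENSG00000115009, chromosome 2, 227805739 to 227817564, plus strand) rose by 5.99 log2 units (5.48 to 6.39 over the 4 libraries), to 485 ± 144 CPM against 7.79 CPM. CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716, plus strand) rose by 5.17 (4.82 to 5.56), to 194 against 5.41 CPM, and TNFAIP6 (ENSG00000123610, chromosome 2, 151357592 to 151380048, plus strand) by 4.2 (3.69 to 5.33), to 147 against 8.29 CPM. IL1B stood at 215 ± 36.9 against 17.6 CPM (log2 3.63), TNF at 70.5 against 6.85 CPM (3.41), CXCL10 at 439 against 21.3 CPM (4.26, from 3.21 to 5.21) and ICAM1 at 110.2 against 8.74 CPM. PTX3 was higher by 4.52 (3.20 to 4.86). MYB fell by 1.73 (-2.50 to -1.41; adjusted p = 1.2e-18), PDK4 by 1.43, from 71.6 to 27.2 CPM, and IGF1 by 1.22, from 48.4 to 21.05 CPM. The rule that named these 25 genes admits only those with 1 direction in all libraries, so that direction is no finding; the highest adjusted p among them was 2.99e-06 (CACNB3). In this fit edgeR took the spread of every gene fully from genes of similar abundance (infinite prior degrees of freedom), and for 21 of the 25 the fitted SE was below the SE between the libraries, at a median ratio of 0.554. With limma voom, which keeps part of each gene's own spread and was run after the data were seen, 708 genes were higher and 278 lower, 896 of the 1345 kept their call, and all 25 were among them. Classes of the same sizes drawn at random from the macrophages 20 times gave a median of 6 and at most 10 genes past the threshold. Classes drawn this way carry no change that could vary between libraries, so they do not test the pooled spread. The number of lower genes was 340 without replicate 1 and 313 without replicate 4. Within clusters, with the cluster in the model, 323 genes were higher and 415 lower of 6274 tested, and 506 of the 1070 called genes tested in both fits remained. That fit used 17 pairs of a cluster and a library over 9 clusters, with at least 10 cells per class. Replicate 2 gave the most pairs, and replicate 3 entered only through the SOD2 cluster. Pairs of the same library were treated as separate, so calls within clusters, here and below, do not rest on independent libraries. Among the named genes tested within clusters, IGF1 (-0.14), ECSCR (-0.43) and AQP3 (-0.45) were no longer past the threshold there; PTX3, CXCL1, NFKB2, SHROOM3, DUSP2, PDGFD and CACNB3 had too few counts to be tested.

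**Figure D3:**
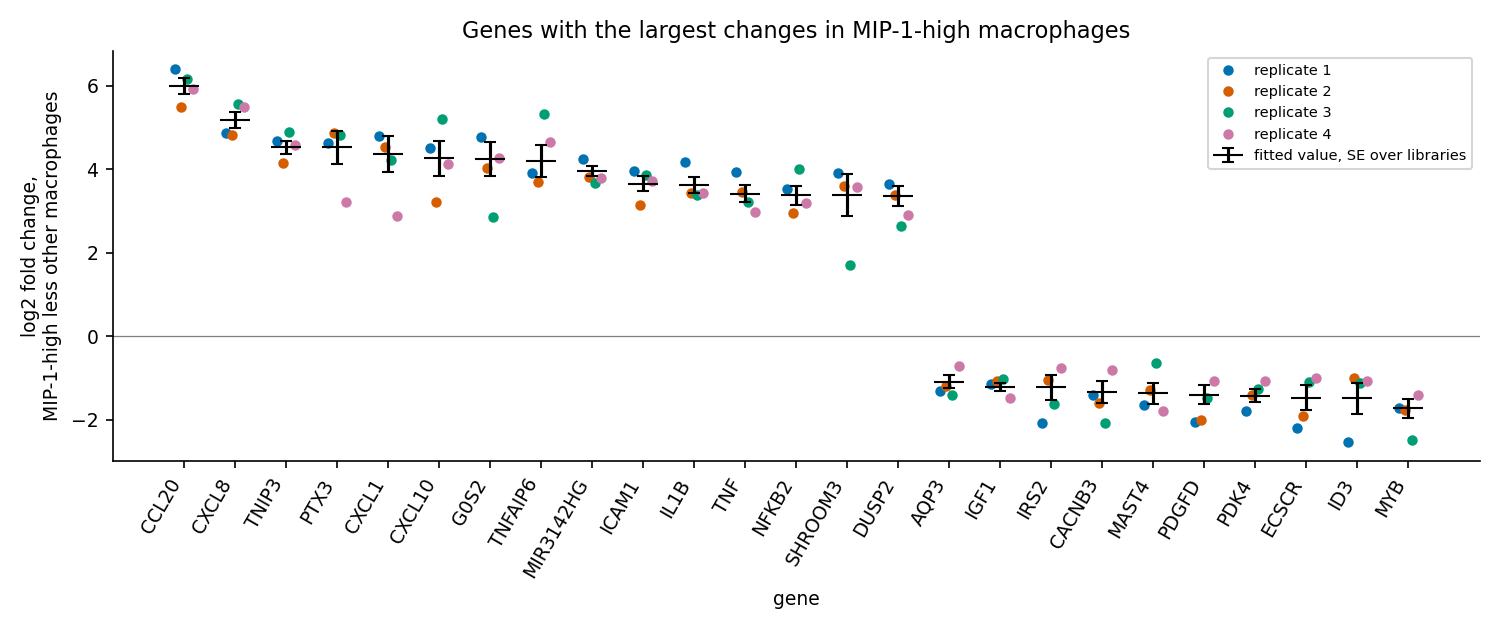
Log2 fold change between MIP-1-high and other macrophages for the 15 largest increases and 10 largest decreases, with a point per replicate and the fitted value with the SE between the 4 libraries. CCL20 reaches 5.99 and MYB -1.73.

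NF-kB targets, the genes that the transcription factor switches on after toll-like receptor or cytokine signals, were all higher in MIP-1-high macrophages. So were most other inflammatory cytokines, CXCL3 among them. The dissociation genes ZFP36, EGR1 and JUNB rose, while 9 members of their list, FOS and JUN among them, did not pass the threshold. Classical activation markers such as SOCS3, IRF1 and TLR2 rose too. Of 26 NF-kB targets tested 26 were higher (26 adjusted over the list alone), with a median log2 fold change of 2.04 (limma camera adjusted p = 1e-61, and 0.0417 with an estimated correlation); MARCKS was higher by 3.09. Of 19 other inflammatory genes 16 were higher (17 adjusted over the list alone), with a median of 1.94 (camera adjusted p = 3.1e-36, and 0.0417 with an estimated correlation). Of 23 immediate early and dissociation genes 14 were higher (15 higher and 1 lower adjusted over the list alone), with a median of 0.57; the camera adjusted p of 4.45e-14 became 0.126 with an estimated correlation. Of 12 classical activation markers 7 were higher (8 higher and 1 lower adjusted over the list alone), SOCS3 by 2.51 and IRF1 by 1.49; the camera adjusted p of 2.45e-07 became 0.0902 with an estimated correlation. With fry the immediate early and dissociation list (adjusted p = 0.0194) and the classical activation, NF-kB and other inflammatory lists (0.00116 for each) were past the threshold upward.

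Single interferon response genes moved in opposite directions, and the result for the list as a whole depended on the test and on the filter. The chemokines CXCL9, CXCL10 and CXCL11 and the guanylate-binding protein GBP1 were higher, while ISG15, IFI6 and IFIT1 were lower. Of 30 genes 6 were higher and 10 lower (8 and 12 adjusted over the list alone). GBP1 was higher by 1.64, CXCL9 by 1.59 and CXCL11 by 2.17. The list's median was -0.09, its mean 0.27 and the direction of its camera test up (adjusted p = 0.987). With fry the list was past the threshold upward (adjusted p = 0.0362), and with camera without the filter on low counts it was past it downward (0.00446). In the fit within clusters CXCL9 turned to -0.16, and without the SOD2 cluster to -0.039; with the DESeq2 test (1.68) and limma voom (1.5) it was not past the threshold.

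Several genes of monocyte-derived macrophages were higher in MIP-1-high cells, and several genes of resident alveolar macrophages lower, but neither list held its call with an estimated correlation (adjusted p = 0.277 for each). CD14, the endotoxin co-receptor, S100A8 and the lysosomal protease LGMN rose, while MCEMP1, GPD1, the gluconeogenic enzyme FBP1 and PPARG, the regulator of alveolar macrophage identity, fell. Of 18 monocyte-derived genes 11 were higher (14 adjusted over the list alone), CD14 by 0.98, LGMN by 0.89 and S100A8 by 0.75. Their median was 0.59, and the camera adjusted p of 1.4e-08 became 0.277 with an estimated correlation. Of 22 resident genes 8 were lower (10 lower and 1 higher adjusted over the list alone), MCEMP1 at -0.89, GPD1 at -0.88, PPARG at -0.47 and FBP1 at -0.44; the camera adjusted p of 6.3e-06 became 0.277 with an estimated correlation. Within clusters S100A8 turned to -0.09, and neither list passed the threshold there (camera adjusted p = 0.688 for the monocyte-derived and 0.493 for the resident genes). With fry, on all macrophages, the monocyte-derived list was not past it either (adjusted p = 0.0737), while the resident list was past it downward (0.0424).

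Some lysosomal, iron and heat shock genes were higher, and some cycling, respiratory and ribosomal genes lower, but none of these lists held its call with an estimated correlation. CTSL, a lysosomal protease, HAMP, which encodes the iron hormone hepcidin, the iron transporter SLC11A2 and the chaperone DNAJB1 were higher. STMN1 and HMGB2, abundant in dividing cells, were lower. Of 22 lysosomal genes 6 were higher and 1 lower (6 and 1 adjusted over the list alone), CTSL by 0.69 and LIPA by 0.45; the camera adjusted p of 0.00351 became 0.543 with an estimated correlation, and 0.0909 without replicate 2, and the direction reversed without the filter on low counts. CTSL was not past the threshold with the DESeq2 test (0.74) or limma voom (0.63). Of 11 iron genes 4 were higher and 1 lower (7 and 1 adjusted over the list alone), HAMP by 1.21, SLC11A2 by 0.95 and SLC11A1 at -0.43; the camera adjusted p of 0.000304 became 0.139 with an estimated correlation. HAMP ranged from 0.24 to 3.66 over libraries and was not past with the DESeq2 test (2.14) or limma voom (0.99). Of 14 heat shock genes 4 were higher and 2 lower (5 and 2 adjusted over the list alone), DNAJB1 by 0.76, HSPA1A by 0.58 and HSPA8 at -0.41; the camera adjusted p of 0.0374 became 0.277 with an estimated correlation, 0.093 without replicate 2 and 0.0539 without replicate 3, and the direction reversed without the filter. Of 18 cell cycle genes 7 were lower (9 adjusted over the list alone), HMGB2 at -0.73 and STMN1 at -0.49; the camera adjusted p of 2.0e-06 became 0.366 with an estimated correlation and 0.105 with doublets kept. Of 22 oxidative phosphorylation genes 3 were lower and 1 higher (3 and 1 adjusted over the list alone), and the camera adjusted p of 0.000168 became 0.404 with an estimated correlation. Of 28 ribosomal protein genes 2 were lower (1 adjusted over the list alone), RPSA at -0.24, not past without replicate 2 (-0.25) or replicate 4 (-0.23); the camera adjusted p of 0.000899 became 0.603 with an estimated correlation, and 0.158 without replicate 3. With fry the lysosomal (adjusted p = 0.143), oxidative phosphorylation (0.0987), ribosomal (0.459) and cell cycle (0.147) lists were not past the threshold either. The iron (0.00421) and heat shock (0.0194) lists were past it upward with fry.

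The remaining lists did not pass the camera threshold, and several held members that moved apart. Among scavenger receptor and lipid genes the oxysterol receptor NR1H3, its target ABCA1 and the fatty acid receptor CD36 were higher and the mannose receptor MRC1 lower. Among complement genes C3 and the anaphylatoxin receptors C3AR1 and C5AR1 were higher, and HIF1A, the hypoxia regulator, was higher beside a lower ALDOA. Scavenger and lipid genes counted 6 higher and 5 lower of 22 (9 and 6 adjusted over the list alone; camera adjusted p = 0.0564, and 0.00160 without replicate 1, 0.0351 without replicate 4 and 0.0412 with DESeq2-style size factors); NR1H3 rose by 1.11, CD36 by 1.13 and ABCA1 by 1.01, and MRC1 stood at -0.65. Complement counted 4 higher of 13 (4 adjusted over the list alone; 0.0698, and 0.00189 without replicate 1), C3AR1 by 1.12 and C3 by 1.12, which turned to -0.06 within clusters. Glycolysis and hypoxia genes counted 5 higher and 3 lower of 16 (5 and 4; 0.258), HIF1A by 1.0 and SLC2A3 by 0.71. MHC class II and antigen presentation genes counted 3 higher and 1 lower of 14 (3 and 2; 0.608), with a median just below 0 (-0.0016), a mean of 0.19 and a test direction of up, but the list was past the threshold downward within clusters (0.00556) and without the filter (0.00446); CD80 rose by 1.57 and CD40 by 0.73. Metallothioneins counted 3 lower of 8 (3 lower and 1 higher; 0.144, and past it downward without replicate 4 (0.0116), without the filter (0.00709) and without T cell marker UMIs (0.00421)), MT1E at -0.44 in 3 of 4 libraries, not past without replicate 2 (-0.24), with the DESeq2 test (-0.38) or limma voom (-0.45), and 0.037 with MIP-1-high cells taken from 1 UMI. Cholesterol synthesis genes counted 1 higher and 2 lower of 19 (1 and 2; 0.403, and 0.00446 downward without the filter), FDFT1 at -0.72. Oxidative stress genes counted 2 higher of 10 (3 and 2; 0.175, and 0.0473 without replicate 1), SQSTM1 by 0.67, and no mitochondrially encoded transcript of 13 passed (0.175 for the list, 6.47e-05 upward without replicate 3, 0.0466 upward with DESeq2-style size factors and 0.017 downward without the filter). Matrix genes counted 3 higher and 2 lower of 12 (4 and 2; 0.187, and 0.0198 without replicate 1), MMP14 by 0.73 and THBS1 at -0.90. Alternative activation markers counted 3 higher and 2 lower of 11 (4 and 2; 0.456), CCL18 by 0.32, which turned to -0.16 within clusters.

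Markers of other cell types were not past the threshold as sets in MIP-1-high macrophages, although single genes that macrophages also express were. The T cell marker IL7R was higher while CD3G was lower. S100A8 and S100A9, shared by neutrophils and monocytes, were higher and MNDA lower. T cell markers counted 1 higher and 1 lower of 7 (1 and 1 adjusted over the list alone; camera adjusted p = 0.388), IL7R by 0.69 and CD3G at -0.85, the latter not past without replicate 2 (-0.63), 3 (-0.77) or 4 (-0.89), with the DESeq2 test (-0.84) or limma voom (-0.78). Neutrophil markers counted 2 higher and 1 lower of 5 (2 and 1; 0.468), S100A9 by 0.29, which turned to -0.15 within clusters, and MNDA at -0.32. Epithelial markers counted 1 lower of 10 (1; 0.328), KRT18 at -1.57, not past without replicate 1 (-1.64) or with the DESeq2 test (-1.60). T cell marker UMIs were present in 41.7% of MIP-1-high and 40.6% of other macrophages, all libraries pooled. By library, T cell markers summed to 113.9 against 72.03 CPM in replicate 1, 121.4 against 95.2 CPM in replicate 2, 161.9 against 165 CPM in replicate 3 and 101.6 against 90.7 CPM in replicate 4, so they were higher in MIP-1-high cells in 3 of 4.

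**Figure D4:**
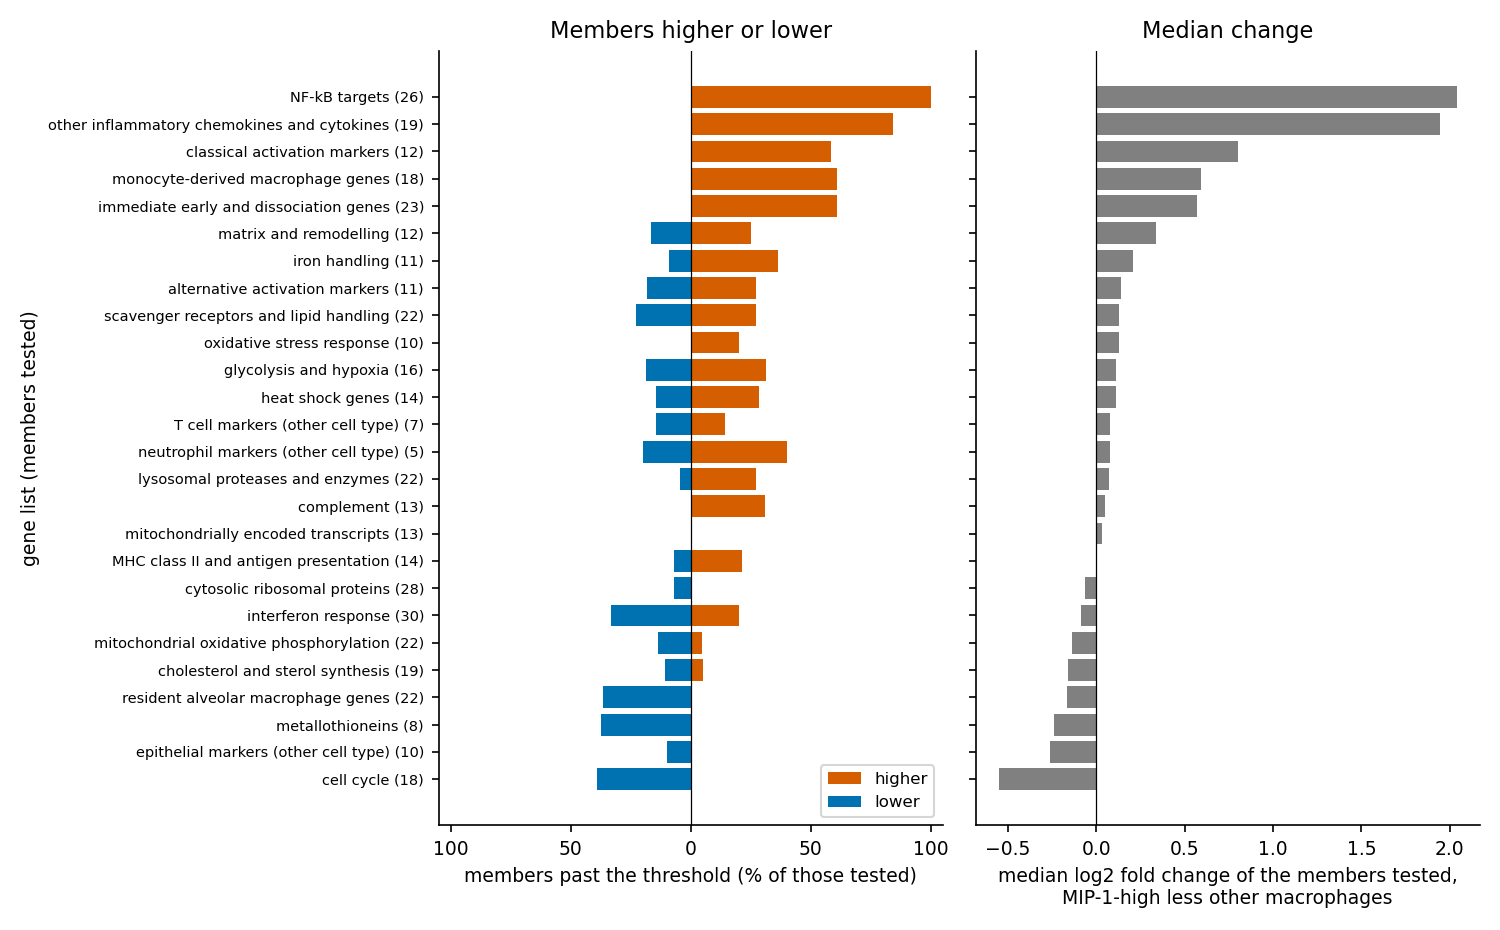
Members of 26 gene lists past the threshold between MIP-1-high and other macrophages, in percent of those tested, and each list's median log2 fold change. NF-kB targets (26 of 26, median 2.04) and other inflammatory genes (16 of 19, median 1.94) stand apart from the rest.

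Macrophages with the strongest interferon response were compared in the same way, and differed in genes outside the response list. They were higher in NEXN, GCH1, the cytokine signalling inhibitor SOCS1, HELZ2, NT5C3A, the RNA sensor DDX58, CD69 and EPSTI1, several of them interferon-induced. They were lower in the lipid genes SMPDL3A and PLTP, in MT1E, CXCR4 and A2M. Interferon-high cells, above the 90th percentile of their library, numbered 2632 against 27130, and of 12339 genes tested (edgeR quasi-likelihood test) 633 were higher and 608 lower; without replicate 2 the number higher was 395, and without replicate 3 it was 400. NEXN rose by 1.74 (adjusted p = 2.5e-16) and SMPDL3A fell by 1.48 (adjusted p = 5.2e-09); 1 direction in all libraries was a condition for naming them. All 28 ribosomal protein genes tested were lower (28 adjusted over the list alone), with a median of -0.28; the camera adjusted p of 3.6e-65 became 0.248 with an estimated correlation. Of 13 mitochondrially encoded transcripts 9 were lower (12 adjusted over the list alone; camera adjusted p = 3.4e-13, and 0.298 with an estimated correlation). Of 11 iron genes 5 were lower (7 adjusted over the list alone; 7.0e-09, and 0.121 with an estimated correlation), and of 8 metallothioneins 6 were (7 adjusted over the list alone; 1.8e-09, and 0.121 with an estimated correlation). Of 4 MIP-1 genes 2 were higher (2 adjusted over the list alone; camera adjusted p = 0.0245, and 0.44 with an estimated correlation). Neutrophil markers counted 3 higher of 5 (3 higher and 1 lower adjusted over the list alone; 0.00663, and 0.44 with an estimated correlation), and T cell (0.562) and epithelial markers (0.875) were not past the threshold. With fry the ribosomal, mitochondrially encoded, iron and metallothionein lists were past it downward (adjusted p = 0.0216 for each). The MIP-1 (0.331) and neutrophil (0.137) lists were not past it with fry. MIP-1-high cells made up 4.72% ± 2.66 (SD, n = 4) of interferon-high and 3.76% ± 2.28 of other macrophages, at 7.09 against 4.31%, 6.75 against 6.59%, 1.56 against 1.20% and 3.47 against 2.95% in replicates 1 to 4. The mean difference of 0.952 percentage points (SD 1.22), from 0.154 to 2.78, came mostly from replicate 1 and was 0.344 without it.

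Metallothioneins bind zinc and copper and rise when these metals are in excess. Macrophages with the most metallothionein transcript were higher in the zinc exporter SLC30A1 and lower in the zinc importer SLC39A10, and also higher in the chemokines CXCL9, CXCL10, CXCL11 and CCL15, in complement C3, IL32 and RGS2. They were lower in the growth factor genes IGF1 and INHBA, and in ECSCR and CISH. Metallothionein-high cells numbered 2588 against 27174, and of 12341 genes tested (edgeR quasi-likelihood test) 325 were higher and 342 lower; without replicate 4 the numbers were 153 and 169. SLC30A1 rose by 1.27 (adjusted p = 8.4e-08) and SLC39A10 fell by 0.99 (adjusted p = 2.6e-09), and CXCL11 rose by 2.80. Of 18 cholesterol synthesis genes 9 were lower (15 adjusted over the list alone), with a median of -0.51; the camera adjusted p of 2.4e-10 became 0.405 with an estimated correlation. Of 22 resident macrophage genes 9 were lower and 1 higher (11 and 2 adjusted over the list alone; 2.2e-09, and 0.405 with an estimated correlation), and of 14 MHC class II and antigen presentation genes 6 were higher (7 adjusted over the list alone; 4.5e-05, and 0.405 with an estimated correlation). Neutrophil markers counted 3 higher of 5 (3 adjusted over the list alone; camera adjusted p = 0.00012, and 0.405 with an estimated correlation), and T cell (0.740) and epithelial markers (0.0935) were not past the threshold. With fry the cholesterol (adjusted p = 0.164), resident (0.126), MHC class II (0.122) and neutrophil (0.139) lists were not past it. MIP-1-high cells made up 3.97% ± 2.23 of metallothionein-high and 3.84% ± 2.30 of other macrophages (SD, n = 4), a mean difference of 0.127 percentage points (SD 0.230), from -0.154 to 0.343.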

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

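The tests of handling, doublets, free MIP-1 RNA and the barcodes almost free of mitochondrial transcripts were chosen only after the results were seen. With 4 libraries, a value was singled out when its gap to the nearest other library was large for the whole range (Dixon's test); 14 of 188 values tested met this, where chance gives about 9.4.

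Several shares of cells stood apart in 1 library. Secretory epithelium-like cells made up 1.79% of kept cells in replicate 4, against 0.664 to 0.824% in the others. B cell-like cells made up 2.87% in replicate 2, against 0.0874 to 0.224%, and unnamed cells 6.49% in replicate 1, against 0.287 to 0.560%. MIP-1 reached 129 CPM in the 328 B cell-like cells of replicate 2, while the other libraries held 26, 7 and 14 such cells without a MIP-1 UMI, which allows up to 67.6, 140.8 and 87.2 CPM in replicates 1, 3 and 4, so a difference from replicate 3 was not detectable at this depth. Among macrophages, the MCEMP1 cluster held 14.2% in replicate 2, against 21.9 to 22.8%, and a small cluster marked by APOC2 and SLC1A3 held 1.95% there, against 0.254 to 0.301%.

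Single genes also stood apart in 1 library, without changing direction. Between MIP-1-high and other macrophages the log2 fold change of PTX3 was 3.20 in replicate 4 (4.63 to 4.86 in the others), of IL1B 4.17 in replicate 1 (3.38 to 3.43), of SHROOM3 1.69 in replicate 3 (3.58 to 3.91) and of ID3 -2.55 in replicate 1 (-1.14 to -1.01). ABCA1 stood at 1.75 in replicate 4 (0.81 to 0.87), SLC2A3 at 1.25 in replicate 2 (0.53 to 0.56) and TXN at -0.37 in replicate 3 (-0.13 to -0.09). Between metallothionein-high and other macrophages RGS2 stood at 1.77 in replicate 4 (0.82 to 0.88). The cause was not tested.

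Barcodes left out for a mitochondrial share of 15% or more held MIP-1 transcripts as well. In these 2873 barcodes the mean was 217 CPM (SD 135, n = 4), from 68.6 to 346 CPM, above the 1.91 to 4.09 CPM that a count of 0 allows. Macrophages of the kept cells held 205 ± 124 CPM.

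The first pattern weighed is the inflammatory set of MIP-1-high macrophages, with CCL20, CXCL8, IL1B and TNF higher and MYB and IGF1 lower. Droplets that hold a macrophage and a lymphocyte are argued against as the whole source. Averaged over the class, NK markers implied at most 0.0704% of NK cell-like RNA, where 1 NK cell-like cell would add at least 12.02%. T cell markers implied at most 1.26% against at least 12.9%, although T cell markers were higher in MIP-1-high cells in 3 of 4 libraries. A minority of such droplets within the class is not excluded by these averages. MIP-1 RNA free in the suspension is argued against as the whole source, since it would mark cells of all clusters alike, while the SOD2 cluster chosen in the other libraries held a share of MIP-1-high cells at least 41.5 points above its share of macrophages (SD 9.79). A response of the cells to lavage and handling may contribute: of 23 immediate early and dissociation genes 14 were higher, with a median log2 fold change of 0.57. This prediction was written after that list had been seen. The list lost its call with an estimated correlation (camera adjusted p = 0.126) but kept it with fry (adjusted p = 0.0194). Of its members 9, FOS and JUN among them, were not past the threshold, so the explanation stays open. An inflammatory state that the macrophages had in the lung would give the same values, and no biological explanation was tested, since the labels give 1 group.

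The second pattern is a set of cells almost free of mitochondrial transcripts, 705 in replicate 1 and 5, 2 and 1 in the other libraries, or 6.08% of the kept cells of replicate 1, with a median of 697 UMIs. They formed a cluster of 540 cells, with SEC11C, HSP90B1, HSPA5 and XBP1 among its leading genes, and another of 173 cells, with PTPRF, TPPP3 and NFIB. The values below take both clusters together. Free RNA in droplets without a cell is argued against, since FTL stood at 3.79%, MALAT1 at 9.14% and B2M at 2.95% of their level over all barcodes of that library. Nuclei without cytoplasm are argued against, since MALAT1, a nuclear transcript, stood at 1269 CPM where the lowest named population held 10726 CPM. RNA of another organism, counted where its sequence matches a human gene, may be the source: the log2 ratio of ribosomal protein genes to T cell-like cells had an SD of 2.05 over genes, where named populations had at most 0.283, and B2M stood at 311 CPM against at least 8231 CPM. These cells had no name and entered none of the comparisons of classes, and no biological explanation was tested.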

How the results depend on the processing

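Doublets by the automatic threshold, limma voom, macrophages without a T cell marker UMI, leaving out the SOD2 cluster, depth-matched references for the interferon-high and metallothionein-high comparisons and leaving out the clusters almost free of mitochondrial transcripts were chosen after the data were seen. Of 309 values of the main results under alternatives, 48 moved beyond the spread between replicates or, for counts, beyond 1.5 times. The other 261 were not counted as moved. For shares with 1 replicate left out this was fixed in advance, since dropping 1 of 4 values moves a mean by less than the SD. The cluster difference of 55.8 percentage points (SD 9.79) was judged by whether the sign-flip test passed the threshold. That test cannot pass with 4 libraries, so the difference could not count as moved. The difference kept its direction in all alternatives, but went beyond its SD to 26.3 (MIP-1-high from 1 UMI), 69.1 (from 10 UMIs) and 84.2 (chemokine genes kept in the clustering). Of 101 named genes past the threshold in the MIP-1-high comparison, 2312 of 2596 values kept direction and call, 267 lost the call and 17 reversed. None of the 1345 genes was past the threshold in the opposite direction under any alternative; 1299 kept their call with DESeq2-style size factors, 735 with the DESeq2 test, 896 with limma voom, 345 without the SOD2 cluster and 860 to 1130 with 1 replicate left out.

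For genes higher in MIP-1-high macrophages (762), the count was 163 without the block, 357 from 10 UMIs, 465 without T cell marker UMIs, 223 without the SOD2 cluster and 323 within clusters. For genes lower (583), it was 1027 without the filter, 8 without the block, 196 with DESeq2, 278 with limma voom, 340 from 10 UMIs, 283 without T cell marker UMIs, 162 without the SOD2 cluster, and 313 (without replicate 4) to 499 (without replicate 3) with 1 replicate left out. For genes higher in interferon-high cells (633), it was 349 without the filter, 0 without the block, 389 with DESeq2 and 395 (without replicate 2) to 507 (without replicate 4) with 1 replicate left out; for genes lower (608), 0 without the block and 303 with DESeq2. For genes higher in metallothionein-high cells (325), it was 0 without the block, 143 with DESeq2 and 153 (without replicate 4) to 253 (without replicate 1); for genes lower (342), 637 without the filter, 0 without the block, 148 with DESeq2 and 169 (without replicate 4) to 281 (without replicate 2). Beside the counts of 0 with edgeR, 408 and 238 genes had an unadjusted p under 0.05 without the block. Fewer cells remained without T cell marker UMIs (12104 removed) and without the SOD2 cluster. From 10 UMIs all cells stayed, but the MIP-1-high class shrank to 347 cells and the rest were counted as other macrophages. For the remaining alternatives the cause was not tested.

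Of the lists, 8 were called higher and 4 lower. Higher were 3 without the filter, 5 without the block, 5 from 10 UMIs, 4 within clusters, 4 without the SOD2 cluster and 2 with an estimated correlation. Lower were 9 without the filter, 2 without the block, 0 with an estimated correlation and 1 with fry. Without the filter 21811 genes were tested and their median log2 fold change was -0.29, against -0.04, and the heat shock (camera adjusted p = 0.381) and lysosomal (0.119) lists reversed. Beside that count of 0, camera with an estimated correlation left no lower list at an unadjusted p under 0.05, the lowest being 0.0814 for the resident genes.

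The share of MIP-1-high macrophages, 3.85%, was 11.6% from 1 UMI and 1.13% from 10 UMIs, by construction. NK cell-like cells made up 0% with at least 1000 UMIs and at a resolution of 0.5; dendritic-like cells 0.210% and unnamed cells 6.50% with at least 1000 UMIs. Pairs of a chemokine gene and a population numbered 42 higher and 50 lower; they were 70 and 82 without the filter and 12 and 25 with at least 1000 UMIs. The cause was not tested.

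Values that reversed were CCL3 in T cell-like cells, to 0.035 at a resolution of 0.5 and 0.40 with at least 1000 UMIs, and, in MIP-1-high cells, KIAA0101 to 0.081 and SPP1 to -0.039 with doublets kept, MT1E to 0.037 and MT1H to 0.10 from 1 UMI, MT1X to 0.075 and FN1 to -0.053 from 10 UMIs, and MT1H to 0.27 above the 90th percentile. Within clusters CXCL9 turned to -0.16, S100A8 to -0.092, C3 to -0.058, CFD to -0.0071, CCL18 to -0.16 and S100A9 to -0.15, and without the SOD2 cluster CXCL9 to -0.039, MT1H to 0.43 and MT1X to 0.36. MT1X ranged from -0.48 (without replicate 2) to 0.018 (without replicate 1). The cause was not tested. Of 31 named chemokine values past the threshold, 396 of 428 kept direction and call, and of 13 genes each in the interferon-high and metallothionein-high comparisons 117 of 130. Depth limits most the lymphocytes, at medians of 867 and 783 UMIs, and few of them (110 and 15) reached the 2000 UMIs at which MIP-1-high cells were counted.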

Other observations

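The swapped-class tests of the MIP-1-high, interferon-high and metallothionein-high comparisons were chosen only after the results were seen. The swapped tests of the populations were written before. The prediction for the depth test of the ribosomal protein genes was written before its result, but the depth-matched reference it uses was chosen after the data were seen.

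Macrophages of these lavages formed further clusters with known genes. A cluster of 652 cells carried the division genes TOP2A, MKI67 and CENPF and held 2.08% ± 0.509 of macrophages (SD, n = 4). A cluster of 1455 cells, led by metallothioneins, held 4.51% ± 1.13, and the SPP1 cluster of 1012 cells 3.1% ± 1.35. Among unnamed cells, 120 formed a cluster with TNFRSF4, IL2RA, TNFRSF18, TIGIT and CTLA4, genes known from regulatory T cells, with 36, 33, 31 and 20 cells in replicates 1 to 4.

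Ribosomal protein transcripts were lower in interferon-high macrophages in all 28 genes of the list, and a difference in depth between the classes is one way to get this. With other macrophages drawn to the same depth, 28 of 28 remained lower past the threshold, at a median log2 fold change of -0.26 against -0.28, which argues against depth as the whole cause. No biological explanation was tested.

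When the classes were swapped within some libraries, in 8 distinct ways with the real one included, the real MIP-1-high classes gave 1345 genes past the threshold and the highest other way 1. The interferon-high classes gave 1241 and 1, and the metallothionein-high classes 667 and 0. For chemokine genes against macrophages, T cell-like cells gave 23 and 0, NK cell-like cells 20 and 0, dendritic-like cells 19 and 3, secretory cells 12 and 4 and ciliated cells 18 and 0. In each of these 1 way of 8, the real one, gave as many, and 8 ways are too few for a share under 0.05.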
